A study of Mus musculus with 11 samples.

How the data were processed

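RNA pulled down with ribosomes tagged in endothelial cells was measured by sequencing in 11 libraries. The adult mice, of the C57BL/6 strain, were either wild type or had both copies of Eltd1 disrupted. Eltd1 is an adhesion G protein-coupled receptor of endothelial cells, and its current symbol is Adgrl4. GL261, a mouse glioma cell line, had been placed in the brain to form tumours. Per the labels' protocols, the mice carried a ribosomal protein, L10a, tagged with green fluorescent protein under the promoter of VE-cadherin, an endothelial gene, and tagged ribosomes were pulled down with antibody-coated beads from dissected tumour or from healthy brain (translating ribosome affinity purification). Ribosomal RNA was then depleted, libraries were prepared with a strand-preserving kit, and only RNA with an integrity number above 7 was used, per the labels' protocols. The groups were tumour of knockout mice (n = 2), tumour of wild type mice (n = 3), brain of wild type mice (n = 3) and brain of knockout mice (n = 3). The protocol speaks of 3 mouse samples in each group, and 2 knockout tumour libraries were analysed here. Replicates are separate mouse samples. Their numbers only name them and pair no samples across groups.

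The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene and library, per the file headers. TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the genome build GRCm38, per the submitters' processing notes; the role of each tool, the gene annotation and whether strand was used are not given in the sources used here. Genes that overlap an antisense transcript, and families of near-identical copies such as histone genes and pseudogenes of ribosomal protein genes, are therefore uncertain. Each library listed 46073 entries. The entries of 211 symbols that occurred more than once, 482 in all, were summed, which left 45802 genes. Positions were taken from a RefSeq table of the same build, which held 14179 of the 15604 tested genes by symbol. The values hold no read counts. Steps of whole reads were looked for in the low values, and between 0.288% and 2.45% of low genes in each pair of libraries lay on the most frequent ratio, so the depth of each library is unknown and no counting interval can be given. Exact zeros occurred for genes that every cell uses, such as 4 of the 13 mitochondrial mRNAs in every library, so a zero can be a failed estimate. For genes at 0 in a whole group, only the value of each library is given.

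Changes were tested on log2(FPKM + 1), with no further scaling, for the 15604 genes with an FPKM of at least 1 in at least 2 libraries. All log2 changes are on this scale, which understates the change of genes with low values. Limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 11 libraries with 7 residual degrees of freedom (lmFit, contrasts.fit and eBayes with a variance trend). The 5 contrasts were tumour minus brain in wild type, tumour minus brain in knockout, knockout minus wild type in tumour, knockout minus wild type in brain, and the difference of the last 2. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The pair of tumour against brain contrasts shares no libraries, and neither does the pair of genotype contrasts. Eltd1 was also compared between genotypes by two-sided exact permutation tests of the mean log2 value. Correlations between contrasts are across genes, which are not independent replicates.

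In each contrast the 12 genes with the largest rise and the 12 with the largest fall were named, among genes that passed, had a mean FPKM of at least 5 in the higher group and did not overlap between the groups. Where under 4 genes passed, the 4 genes with the smallest p in each direction were named instead, as passing or not. Predicted, clone-named, mitochondrial rRNA and pseudogene symbols were counted but not named. Adgrl4 was named everywhere, with 2 to 4 members of each list, taken by smallest p, and single values of 2 list members are not reported here. The 20 gene lists covered endothelial identity, the blood-brain barrier, endothelial Wnt/beta-catenin targets, tip cell and sprouting, Notch pathway, VEGF and angiopoietin receptors and ligands, basement membrane and matrix, leukocyte adhesion, chemokines, interferon response, antigen presentation, immune checkpoint ligands, NF-kB and inflammatory activation, cell proliferation, hypoxia and glycolysis, TGF-beta and mesenchymal transition, arterial, venous, adhesion GPCR, and immediate early and stress genes. A further 10 lists held markers of mural cells, fibroblasts, neurons, astrocytes, oligodendrocytes, microglia and macrophages, lymphocytes, erythrocytes, choroid plexus and ependyma, and neural progenitor and glioma cells. Groups, contrasts, lists, the naming rule and most alternative settings were fixed before the data were examined. Lists can share genes, and of the tested members 0 of 10 neuron, 0 of 9 oligodendrocyte, 5 of 27 blood-brain barrier, 10 of 24 endothelial identity, 9 of 13 VEGF and 9 of 22 tip cell genes are in another list. Lists with at least 5 tested members, 27 in all, were tested with camera of limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 27 lists of a contrast. Camera compares a list with all other genes. The list values given as relative are the mean log2 change of the members minus the mean over all tested genes. Camera with a correlation estimated from the data, and fry, which asks whether the members move on balance in 1 direction, were alternatives.

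The settings fixed in that way were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 FPKM, scaling by the upper quartile, quantile normalization, rescaling to 1 common sum, no or a robust variance trend, weights per library, fits to only the groups compared, a minimum log2 change of 1, keeping the highest of repeated entries, and leaving out each library in turn. In the fits that leave 1 knockout tumour library, that sample is assumed to vary like the other groups. Chosen after the data were seen were leaving out an interval of chromosome 8, the mean of the neuron list as a covariate, the presence of Y-linked transcripts as a covariate (Ddx3y of at least 1 FPKM, in 2 of 2 knockout and 2 of 3 wild type tumours, and 2 of 3 knockout and 1 of 3 wild type brains), and leaving out wild type tumour replicates 2 and 3 together.

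The tests were run on simulated data built on the same 15604 genes. Genes changed by 1, 2 and 3 on the log2 scale numbered 67, 67 and 66. For tumour against brain in wild type, 0%, 14.9% and 34.8% of them were recovered with 0 false calls. In knockout, tumour against brain gave 0%, 2.99% and 28.8% with 3 false calls. Knockout against wild type gave 1.49%, 2.99% and 24.2% with 1 false call in tumour, and 1.49%, 14.9% and 48.5% with 4 false calls in brain. The difference of the genotype effects gave 0%, 0% and 0% with 0 false calls. A shifted blood-brain barrier list was recovered in each of the 5 contrasts, with 0 of the 26 other lists passing. The simulation sets no rate of false gene or list calls in real data, where genes can vary together or be 0 in whole groups.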

Results

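Transcripts on endothelial ribosomes were compared between gliomas and healthy brain, and between wild type and Eltd1 knockout mice. The 11 libraries came from knockout tumours (n = 2), wild type tumours (n = 3), wild type brains (n = 3) and knockout brains (n = 3), each a separate mouse sample, and the deposited values were FPKM. FPKM sums ran from 477911 in wild type tumour replicate 3 to 641665 in wild type tumour replicate 2, and the number of genes above 0 from 8978 in wild type tumour replicate 2 to 15433 in wild type brain replicate 3. Sequencing depth is unknown. Tissue separated the libraries on the first principal component, which held 46.5% of the variance, with all 5 tumour libraries below 0 and all 6 brain libraries above 0. Across genes, Pearson correlations lay between 0.713 and 0.897 for tumour libraries of the same group, between 0.774 and 0.873 for brain libraries of the same group, and between 0.513 and 0.774 for a brain against a tumour library. A pair of wild type tumour libraries stood apart. Replicate 2 had 25.4% of 10853 expressed genes at 0, and replicate 3 held Snap25, a synaptic transcript of neurons, at 2083 FPKM, 61.7% of its mean in brain.

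Adgrl4, the current symbol of Eltd1, lies on chromosome 3 from 151437882 to 151545081 in GRCm38. Its FPKM was 11.5 and 5.82 in knockout tumours, against 45.0, 192 and 27.4 in wild type tumours. In brain it was 21.6, 23.6 and 22.2 in knockouts and 166, 82.7 and 153 in wild types. Every knockout library was thus below every wild type library of its tissue, at 9.81% of the wild type mean in tumour and 16.8% in brain. The log2 difference was -2.78 (SE 0.69, n = 2 and 3) in tumour and -2.46 (SE 0.62, n = 3 and 3) in brain, and neither passed limma's adjustment over all genes (adjusted p = 0.901 and adjusted p = 1). The exact two-sided permutation p was 0.2 in tumour (n = 2 and 3) and 0.1 in brain (n = 3 and 3), where 0.1 is the smallest that either design allows. With labels exchanged within each tissue and both tissues combined, the exact permutation p was 0.01, where 0.005 is the smallest value possible. The disrupted part of the gene is not given in the sources used here, so the remaining FPKM was not assigned to exons.

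**Figure D1:**
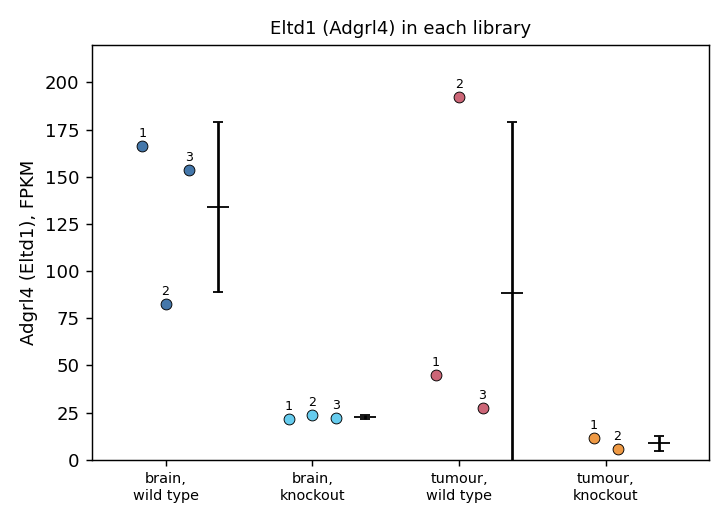
FPKM of Adgrl4 (Eltd1) in each library by group, with numbered points for replicates and the black bar for the mean ± SD of the group. Knockout libraries lie between 5.82 and 23.6, and wild type libraries between 27.4 and 192.

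Tumour and brain of wild type mice were compared in RNA pulled down with tagged ribosomes. Cell cycle and antigen presentation genes were far higher in tumour. Top2a, the DNA topoisomerase of dividing cells, stood at 392 ± 120 FPKM in tumour and 1.44 ± 1.76 in brain (SD, n = 3 and 3; log2 change 7.52, SE 0.58, adjusted p = 7.21e-05). Gbp2, an interferon-induced GTPase, stood at 694 ± 211 against 29.6 ± 11.3 FPKM (SD, n = 3 and 3; log2 change 4.53, SE 0.38). Blood-brain barrier transcripts were far lower, and endothelial identity genes too, so a smaller endothelial share of tumour RNA cannot be told apart. Slco1a4, an organic anion transporter of brain endothelium, stood at 17.3 ± 13.5 against 343 ± 10.3 FPKM, and Bsg, a barrier glycoprotein, fell by 2.96 on the log2 scale (SE 0.29, adjusted p = 0.000191).

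Limma called 3024 of 15604 genes at an adjusted p under 0.05, 1201 higher and 1823 lower in tumour, and 5362 genes had an unadjusted p under 0.05. Among the largest rises were Cdk1, the mitotic kinase, with a log2 change of 6.91 (SE 0.51), the imprinted RNA H19 with 7.68 (SE 0.66), the macrophage and tumour glycoprotein Gpnmb with 6.98 (SE 0.54), and the MHC class II genes H2-Eb1 with 6.79 (SE 0.59) and H2-Ab1 with 6.48 (SE 0.65). Cd74, the MHC class II invariant chain, was listed at 265, 301 and 69.8 FPKM in tumour and at 0 in the 3 brain libraries. The ubiquitin-like Ubd (170, 120 and 44.2 FPKM), the spindle protein Prc1 (110, 103 and 69.5 FPKM) and the histone Hist1h2bl (206, 512 and 143 FPKM) also rose and were listed at 0 in brain. The histones Hist2h2bb and Hist1h2af rose by 7.03 (SE 1.17) and 6.47 (SE 0.67). Among the largest falls were the mitochondrial mRNAs mt-Co1 with -6.74 (SE 0.61) and mt-Nd1 with -6.12 (SE 0.67), and mt-Nd4 was listed at 0 in tumour and at 41.5, 81.2 and 28.6 FPKM in brain. The synaptic vesicle gene Syp fell by 5.84 (SE 1.36), Lamp5 by 5.81 (SE 0.93), Mgp, matrix Gla protein, by 5.38 (SE 0.78), and Atp1b1, a sodium pump subunit, by 5.37 (SE 1.44). Syp no longer passed without wild type tumour replicate 1 (adjusted p = 0.0524), nor did Atp1b1 without that library (0.0568) or without wild type brain replicate 1 (0.0561), 2 (0.0722) or 3 (0.0567), with a pseudocount of 0.1 (0.0656) or with no filter (0.0505). The other large falls, Cox4i1 (listed at 0 in tumour and at 396, 173 and 163 FPKM in brain), Emc8 with -5.79 (SE 1.30), Tcf25 with -5.63 (SE 1.20), Map1lc3b with -5.46 (SE 1.12) and Cbfa2t3 (0 in tumour and 75.2, 28.9 and 22.8 FPKM in brain), lie in an interval of chromosome 8 where 50 expressed genes were listed at 0 in wild type tumour replicates 1 and 3. In a fit of the wild type libraries alone, Syp (0.113), Lamp5 (0.0576), Atp1b1 (0.145), Emc8 (0.107), Tcf25 (0.0991) and Map1lc3b (0.0920) were lost. Adgrl4 had a log2 difference of -1.03 (SE 0.62, adjusted p = 0.262), which passed without wild type tumour replicate 2 (adjusted p = 0.0196) and with library weights (0.0134). The count was 1796 without wild type tumour replicate 1, 1916 without wild type brain replicate 1 and 1933 without wild type brain replicate 2. It was 614 (429 higher) in a fit of the 6 wild type libraries alone, 4937 with library weights and 0 with the neuron list as a covariate (1119 at an unadjusted p under 0.05). Of the calls, 39.7% were higher in tumour, against 51.8% after scaling by the upper quartile and 52.2% after quantile normalization. The median over all genes moved from -0.26 to -0.10 and 0.01, and list values are therefore given relative to all tested genes.

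Brain endothelial lists were lower in wild type tumours. Of 27 blood-brain barrier genes, 17 fell, 0 rose and 10 did not pass, and 21 fell adjusted over the list alone. The list lay -1.89 relative to all genes (camera adjusted p = 1.84e-10; adjusted p = 0.0238 with an estimated correlation). Beside Slco1a4 and Bsg, Itm2a fell by 3.05 (SE 0.33) and Spock2 by 3.10 (SE 0.37). Of 24 endothelial identity genes, 8 fell, 0 rose and 16 did not pass (15 fell adjusted over the list alone), and the list lay at -1.32 (adjusted p = 8.47e-06; adjusted p = 0.0325 with an estimated correlation). Tek, the angiopoietin receptor, fell by 2.96 (SE 0.37), Flt1, a VEGF receptor, from 104 ± 36.0 to 15.6 ± 4.09 FPKM (SD, n = 3 and 3), and Cldn5, the tight junction claudin, from 383 ± 59.6 to 96.3 ± 34.5 FPKM. Of 14 endothelial Wnt/beta-catenin targets, 8 fell and 0 rose (9 fell adjusted over the list alone), led by the feedback inhibitors Nkd1 with -3.15 (SE 0.42) and Apcdd1 with -1.98 (SE 0.35) and the transcription factor Lef1 with -1.87 (SE 0.35). That list lay at -1.17 (adjusted p = 0.00194; adjusted p = 0.0533 with an estimated correlation). Of 13 arterial genes, 5 fell and 0 rose (9 fell adjusted over the list alone), with Mgp, the ephrin Efnb2 at -3.42 (SE 0.67) and the kinase Bmx at -3.03 (SE 0.71). The arterial list lay at -2.19 (adjusted p = 0.000831; adjusted p = 0.138 with an estimated correlation). Of 12 venous genes only Car4 fell, by 5.01 (SE 0.81), 0 rose, the same count held adjusted over the list alone, and the list did not pass (-0.33, adjusted p = 0.729). In the Notch pathway 1 of 13 genes fell, Efnb2, with the same count adjusted over the list alone. Its relative value was -1.10 (adjusted p = 0.0355; adjusted p = 0.218 with an estimated correlation), and it did not pass without wild type tumour replicate 3 (0.0788) or wild type brain replicate 1 (0.0995). Of 13 VEGF and angiopoietin genes, 4 fell and 0 rose, and adjusted over the list alone 8 fell and 2 rose. Tek, Flt1, the phosphatase Ptprb with -3.69 (SE 0.66) and the receptor Tie1 with -1.61 (SE 0.42) were the 4. The list lay at -0.70 (adjusted p = 0.0354; adjusted p = 0.116 with an estimated correlation), lost without wild type tumour replicate 3 (0.129) or wild type brain replicate 2 (0.0546). Of 17 adhesion GPCR genes, 9 fell and 2 rose (12 and 3 adjusted over the list alone), with Adgrf5 at -2.51 (SE 0.37) and Adgrl1 at -3.46 (SE 0.80), and Adgrg6 at 2.86 (SE 0.55) and Adgra3 at 2.14 (SE 0.45). Their list lay at -1.20 (adjusted p = 0.0172; adjusted p = 0.157 with an estimated correlation). Of 13 leukocyte adhesion genes, 3 fell and 0 rose, also adjusted over the list alone, namely Cd99l2 with -2.81 (SE 0.61), Pecam1 with -1.97 (SE 0.46) and Jam2 with -2.31 (SE 0.58), and the list did not pass (-0.77, adjusted p = 0.116). Neuron markers were lower too, as given below.

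Proliferation, interferon and antigen presentation lists were higher in wild type tumours. Of 25 cell proliferation genes, 23 rose and 0 fell (24 rose adjusted over the list alone), among them Cdk1, Top2a, and Cdc20 and Ccnb1, both with 6.40 (SE 0.50 and 0.55), which drive mitosis. Proliferation lay at 5.16 (adjusted p = 4.28e-25; adjusted p = 0.0135 with an estimated correlation). Of 30 interferon response genes, 20 rose and 0 fell, also adjusted over the list alone. The interferon list lay at 2.67 (adjusted p = 2.17e-16; adjusted p = 0.0135 with an estimated correlation). Besides Gbp2, the GTPase Igtp rose by 4.75 (SE 0.51). Of 16 antigen presentation genes, 14 rose and 0 fell, also adjusted over the list alone, with Cd74, H2-Eb1 and H2-Ab1 first. The antigen presentation list lay at 3.81 (adjusted p = 3.44e-14; adjusted p = 0.0319 with an estimated correlation). Of 8 immune checkpoint ligands, 3 rose and 0 fell (4 rose and 1 fell adjusted over the list alone), namely Lgals9 with 3.08 (SE 0.37), Cd274, which encodes PD-L1, with 2.72 (SE 0.72), and Ido1 with 2.71 (SE 0.82). The list lay at 1.26 (adjusted p = 0.0445; adjusted p = 0.277 with an estimated correlation) and did not pass without wild type tumour replicate 1 (0.0723) or 2 (0.0901) or wild type brain replicate 2 (0.0546) or 3 (0.0870). Of 14 NF-kB and inflammatory genes, 3 rose and 0 fell, also adjusted over the list alone, namely Nfkb2 with 2.73 (SE 0.42), Socs3 with 3.09 (SE 0.49) and Irf1 with 3.26 (SE 0.55). That list lay at 1.03 (adjusted p = 0.0317; adjusted p = 0.114 with an estimated correlation) and did not pass without wild type tumour replicate 2 (0.0543) or wild type brain replicate 3 (0.0541). Microglia and macrophage markers rose in the same libraries, with 5 of 14 members, as did Lck, a lymphocyte kinase, and 4 of 8 glioma cell markers, Olig2 and Cd44 among them.

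Of 22 tip cell and sprouting genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The sprouting peptide Apln stood at 67.5 ± 32.5 against 2.86 ± 1.51 FPKM (SD, n = 3 and 3), Mcam, an adhesion molecule, rose by 3.00 (SE 0.42), Trp53i11 by 1.91 (SE 0.41), and the growth factor Pdgfb fell by 1.45 (SE 0.39). Tip cell genes lay at 0.96 (adjusted p = 0.010; adjusted p = 0.116 with an estimated correlation). Of 23 basement membrane and matrix genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with the collagen Col3a1 at 3.46 (SE 0.57), the protease Mmp2 at 2.78 (SE 0.63) and the laminin Lamb1 at 3.01 (SE 0.71), and Sparcl1 at -2.60 (SE 0.44). This list lay at 0.98 (adjusted p = 0.0205; adjusted p = 0.0834 with an estimated correlation) and did not pass without wild type brain replicate 3 (0.0520). Of 18 hypoxia and glycolysis genes, 2 rose and 3 fell, also adjusted over the list alone. The glycolytic Pgk1 and Hk2 rose by 1.27 (SE 0.30) and 2.68 (SE 0.66), and the glucose transporter Slc2a1 fell by 1.64 (SE 0.36). The hypoxia list did not pass (adjusted p = 0.729), and its mean of -0.23 lay below 0 while its median of 0.03, its relative value of 0.04 and the test lay above. Of 18 TGF-beta and mesenchymal genes, 2 rose, Vim with 2.38 (SE 0.27) and Tgfbi with 4.59 (SE 0.73), and 4 fell, led by Id1 with -2.46 (SE 0.35), also adjusted over the list alone. That list did not pass (adjusted p = 0.853), with a mean of -0.13 and the test below 0 and a relative value of 0.14. Of 9 chemokines, Cxcl12 and Cx3cl1 fell by 4.05 (SE 0.39) and 4.08 (SE 1.03) and 0 rose (2 fell and 1 rose adjusted over the list alone), and the list did not pass (0.31, adjusted p = 0.749). Of 12 immediate early and stress genes, 3 fell and 0 rose, also adjusted over the list alone, the phosphatase gene Dusp1, Egr1 with -1.26 (SE 0.37) and Zfp36 with -2.46 (SE 0.76). The immediate early list did not pass (-0.52, adjusted p = 0.236).

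Markers of other cell types also differed between wild type tumour and brain. Of 10 neuron markers, 9 fell and 0 rose (10 fell adjusted over the list alone), with Rbfox3 at -4.91 (SE 0.95), Slc17a7 at -4.15 (SE 0.87) and Syt1 at -3.18 (SE 0.68). Neuron markers lay at -3.57 (adjusted p = 4.29e-05; adjusted p = 0.198 with an estimated correlation). Of 9 oligodendrocyte markers, 4 fell and 0 rose (8 fell adjusted over the list alone), with the myelin genes Mal at -3.79 (SE 0.74) and Mog at -3.66 (SE 0.89). Oligodendrocyte markers lay at -1.90 (adjusted p = 0.00217; adjusted p = 0.277 with an estimated correlation). Of 9 astrocyte markers, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with the glutamate transporter Slc1a2 at -4.32 (SE 0.96) and Gfap at 1.65 (SE 0.48). The astrocyte list did not pass (-1.28, adjusted p = 0.0719), except without wild type tumour replicate 3 (0.0425) or replicates 2 and 3 (0.0131), with no filter (0.0481), after quantile normalization (0.0497) and with fry (0.00613). Of 14 microglia and macrophage markers, 5 rose and 0 fell (6 rose adjusted over the list alone), with Lyz2 at 4.93 (SE 0.79), the complement gene C1qc at 3.61 (SE 0.80), and Ptprc at 5.08, 13.1 and 2.26 FPKM in tumour and listed at 0 in brain. Their list lay at 2.19 (adjusted p = 4.96e-05; adjusted p = 0.0224 with an estimated correlation). Of 8 neural progenitor and glioma cell markers, 4 rose and 1 fell (4 and 2 adjusted over the list alone). Olig2 stood at 81.7 ± 27.0 against 5.52 ± 2.21 FPKM (SD, n = 3 and 3), Cd44 rose by 4.08 (SE 0.64) and Prom1 fell by 2.84 (SE 0.81). This list did not pass (1.18, adjusted p = 0.0523), except without wild type brain replicate 1 (0.0225) or knockout brain replicate 1 (0.0463), with no filter (0.0419), with a filter of 5 FPKM (0.0334) and with fry (0.000132). Of 12 mural cell markers, Cspg4 rose by 2.08 (SE 0.53) and 0 fell, also adjusted over the list alone (list 0.51, adjusted p = 0.303). Of 6 fibroblast markers, Col3a1 rose and Fbln1 fell by 1.72 (SE 0.53), also adjusted over the list alone. The fibroblast list did not pass (adjusted p = 0.998), with a mean of -0.25 and a median of -1.17 but a relative value of 0.02. Of lists too small to test, 1 of 3 lymphocyte markers rose, Lck with 3.73 (SE 0.60), while 0 of 3 erythrocyte and 0 of 4 choroid plexus and ependyma markers passed. Adjusted over the list alone, the lymphocyte and erythrocyte counts were the same, and of the choroid plexus list Clic6 was higher and Ttr lower. Of the lists that did not pass in wild type, leukocyte adhesion (adjusted p = 0.00351), venous (0.00911) and immediate early genes (0.010) passed with fry, leukocyte adhesion with a filter of 5 FPKM (0.0495) and mural markers without wild type tumour replicates 2 and 3 (0.0394). Of those that passed, tip cell (0.26, adjusted p = 0.309), matrix (0.42, 0.386), NF-kB (0.29, 0.423), adhesion GPCR (-0.41, 0.419) and Notch lists (0.122) were lost with the neuron covariate, where checkpoint ligands turned to -0.26 (0.962). Checkpoint ligands were also lost with a pseudocount of 0.1 (0.0549), upper quartile scaling (0.0539), quantile normalization (0.0582), wild type libraries alone (0.0539) and the Y-linked covariate (0.109), and Notch after quantile normalization (0.0579) and without wild type tumour replicates 2 and 3 (0.0976).

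**Figure D2:**
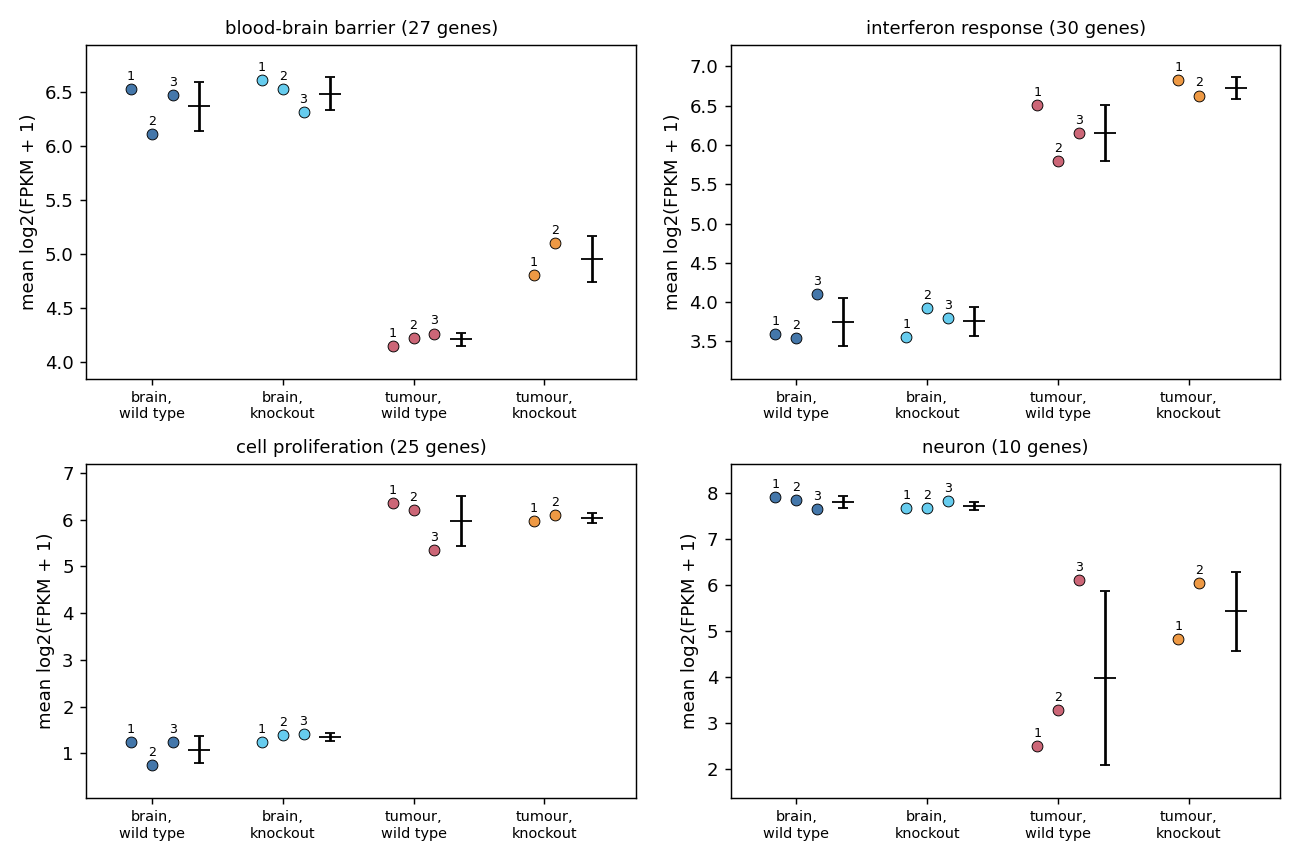
Mean log2(FPKM + 1) over the members of 4 gene lists in each library, with numbered points for replicates and the black bar for the mean ± SD of the group. Blood-brain barrier values are 4.15 to 5.10 in tumour and 6.11 to 6.61 in brain libraries, and wild type tumour replicate 3 has a neuron value of 6.10.

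In knockout mice, tumour (n = 2) was compared with brain (n = 3), with the same limit. MHC class II genes were among the largest rises. H2-Ab1 and H2-Eb1 rose by 8.23 (SE 0.72) and 8.00 (SE 0.66), and Cd74 stood at 333 and 286 FPKM in tumour against 2.07, 0.43 and 0.47 in brain. Gbp2 stood at 858 and 958 FPKM in tumour against 17.3, 14.0 and 28.8 in brain (log2 change 5.49, SE 0.43, n = 2 and 3, adjusted p = 0.000255). Barrier genes were lower, with Bsg at 482 ± 72.1 against 2483 ± 384 FPKM (SD, n = 2 and 3; log2 change -2.36, SE 0.32, adjusted p = 0.00176).

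Limma called 1105 genes, 748 higher and 357 lower in knockout tumour, and 3837 genes had an unadjusted p under 0.05. The other large rises were Gpnmb with 7.88 (SE 0.60), Moxd1 with 6.95 (SE 0.79), the matrix protein Emilin1 with 6.93 (SE 0.64), the mitotic activator Cdc20 with 6.74 (SE 0.56), the neurofilament-like Prph with 6.64 (SE 0.93), and the histones Hist1h2bn with 6.83 (SE 1.18), Hist1h2af (91.8 and 140 FPKM), Hist1h1a (110 and 116 FPKM) and Hist1h2bm (154 and 65.2 FPKM), the last 3 listed at 0 in brain. The large falls were Ttr, the transthyretin of choroid plexus (listed at 0 in tumour and at 146, 106 and 81.5 FPKM in brain), mt-Nd2 (0, and 63.0, 35.9 and 22.9), Samd12 (0, and 55.6, 26.7 and 27.9), Hapln2 (0, and 42.0, 9.59 and 17.6). Further falls were mt-Nd1 with -5.44 (SE 0.75), mt-Co1 with -5.05 (SE 0.68), and the vesicular glutamate transporter Slc17a6 with -4.75 (SE 0.81). They also held the imprinted RNAs Rian with -4.69 (SE 0.84) and Meg3 with -4.34 (SE 0.75), Cxx1c with -4.64 (SE 1.18), the calcium channel subunit Cacnb4 with -4.35 (SE 0.95) and Arhgdig with -4.31 (SE 0.93). Adgrl4 had a log2 difference of -1.35 (adjusted p = 0.251), which passed with library weights (0.0286). The count was 163 without knockout tumour replicate 1 and 261 without replicate 2, fits in which the remaining knockout tumour library is assumed to vary like the other groups. It was 2004 without wild type tumour replicate 2, 1859 (912 higher) without wild type tumour replicate 3, and 550, 559 and 563 without knockout brain replicates 1, 2 and 3. Without knockout tumour replicate 1, Hist1h2bn, Hist1h2bm, Ttr, mt-Nd2, Slc17a6, Rian, Cxx1c, Hapln2, Cacnb4, Meg3 and Arhgdig no longer passed (adjusted p of 0.0813 to 0.351), nor did Hist1h2bn, Hist1h2bm, Ttr, mt-Nd2, Cxx1c, Hapln2 and Cacnb4 without replicate 2 (0.0702 to 0.168). Of these, Hist1h2bm, mt-Nd2 and Cxx1c were also lost without each knockout brain library, Hapln2 without replicates 1 and 3, Cacnb4 without 1 and 2, and Arhgdig without each (0.0533 to 0.116), and Cxx1c without wild type brain replicate 3 (0.0569). With a pseudocount of 0.1, mt-Co1 (0.0602), Meg3 (0.0554), Arhgdig (0.0946), mt-Nd2, Cxx1c and Cacnb4 (0.0718 to 0.167) were lost, with the neuron covariate 10 of the 24 passed (mt-Co1 at 0.0562), and Cxx1c was lost in 4 further settings (0.0513 to 0.0719) and mt-Nd2 in 2 (0.0653 and 0.0683). The count was also 710 with a pseudocount of 0.1, 1822 after quantile normalization, 4126 (1864 higher) with library weights, 2803 (1321 higher) in a fit of the 5 knockout libraries alone, 114 with the neuron list as a covariate, and 2750 (1209 higher) without wild type tumour replicates 2 and 3, so that fewer were higher than lower in 4 of these settings.

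Of 27 blood-brain barrier genes, 10 fell and 0 rose (15 fell adjusted over the list alone), among them Itm2a with -3.05 (SE 0.37), Spock2 with -2.79 (SE 0.41) and Slco1a4 with -3.53 (SE 0.54). Barrier genes lay at -1.44 (adjusted p = 2.36e-08; adjusted p = 0.0221 with an estimated correlation), while neuron (-2.20) and oligodendrocyte markers (-1.58) lay lower in the same libraries. Of 24 endothelial identity genes, 3 fell and 0 rose, also adjusted over the list alone, Flt1 with -2.25 (SE 0.41), Tek with -2.26 (SE 0.41) and Cldn5 with -1.89 (SE 0.35). Endothelial identity lay at -1.15 (adjusted p = 1.81e-05; adjusted p = 0.0246 with an estimated correlation). Of 14 Wnt/beta-catenin targets, 4 fell and 0 rose (8 fell adjusted over the list alone), among them Nkd1 with -3.04 (SE 0.47), Lef1 with -1.97 (SE 0.39), and Notum, listed at 0 in tumour and at 9.18, 4.29 and 15.9 FPKM in brain. The Wnt list lay at -1.43 (adjusted p = 4.74e-05; adjusted p = 0.0189 with an estimated correlation). Of 13 arterial genes, Bmx and Mgp fell by 3.23 (SE 0.79) and 3.53 (SE 0.87) and 0 rose (3 fell adjusted over the list alone), with the list at -1.69 (adjusted p = 0.00350; adjusted p = 0.207 with an estimated correlation). Of 17 adhesion GPCR genes, Adgra3 and Adgrg6 rose by 2.74 (SE 0.51) and 2.40 (SE 0.61) and Adgrf5 fell by 1.97 (SE 0.41), and adjusted over the list alone 2 rose and 4 fell. The adhesion GPCR list lay at -0.82 (adjusted p = 0.0436; adjusted p = 0.217 with an estimated correlation) and did not pass without knockout tumour replicate 1 (0.0638) or 2 (0.0540), wild type brain replicate 1 (0.0540), 2 (0.0541) or 3 (0.0517), or knockout brain replicate 1 (0.0513) or 2 (0.0767). Of 13 VEGF and angiopoietin genes, Angpt2, an angiopoietin of remodelling vessels, rose by 3.54 (SE 0.86) and Flt1 and Tek fell (2 rose and 3 fell adjusted over the list alone), and the list did not pass (-0.28, adjusted p = 0.131). In the Notch pathway 0 of 13 genes passed, also adjusted over the list alone, and the list did not pass (adjusted p = 0.343), like the venous list (0 of 12, and 1 lower adjusted over the list alone, adjusted p = 0.378) and leukocyte adhesion (0 of 13, and 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.378).

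Of 25 proliferation genes, 21 rose and 0 fell in knockout tumours (25 rose adjusted over the list alone), with Cdc20, Ccnb1 at 6.21 (SE 0.61), and Top2a at 435 ± 123 against 4.87 ± 3.79 FPKM (SD, n = 2 and 3). Proliferation lay at 4.77 (adjusted p = 1.08e-26; adjusted p = 0.00750 with an estimated correlation). Of 30 interferon response genes, 19 rose and 0 fell (25 rose adjusted over the list alone), with Gbp2, and Gbp7 at 4.13 (SE 0.41). The interferon list lay at 3.06 (adjusted p = 9.81e-23; adjusted p = 0.00513 with an estimated correlation). Of 16 antigen presentation genes, 14 rose and 0 fell (16 rose adjusted over the list alone), led by H2-Eb1, H2-Ab1 and Cd74. The antigen list lay at 4.45 (adjusted p = 5.13e-21; adjusted p = 0.0108 with an estimated correlation). Of 8 checkpoint ligands, 3 rose and 0 fell (4 rose adjusted over the list alone), Lgals9 with 2.77 (SE 0.41), Ido1 with 4.31 (SE 0.91) and Cd274 with 3.14 (SE 0.81). Checkpoint ligands lay at 2.18 (adjusted p = 0.00137; adjusted p = 0.137 with an estimated correlation). Of 14 NF-kB genes, 4 rose and 0 fell (5 rose adjusted over the list alone), Nfkb2 with 2.74 (SE 0.47), Socs3 with 2.99 (SE 0.54), Irf1 with 3.16 (SE 0.62) and Il1b, listed at 3.64 and 5.94 FPKM in tumour and 0 in brain. The NF-kB list lay at 1.22 (adjusted p = 0.00137; adjusted p = 0.0246 with an estimated correlation). Of 9 chemokines, Cxcl10 (55.0 and 23.2 FPKM in tumour, 0 in brain) and Cxcl9 (14.1 and 8.13 FPKM, 0 in brain) rose and Cxcl12 fell by 3.13 (SE 0.43), also adjusted over the list alone, and the list did not pass (1.37, adjusted p = 0.127). Macrophage markers were higher in the same libraries, with C1qa at 134 and 102 FPKM against 5.48, 15.6 and 4.94 in brain, as were 3 of 8 glioma markers.

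Of 22 tip cell genes, 6 rose and 0 fell in knockout tumours (9 rose adjusted over the list alone). Mcam stood at 490 ± 79.1 against 22.9 ± 13.8 FPKM (SD, n = 2 and 3), Apln rose by 4.03 (SE 0.60), Igfbp3 by 2.74 (SE 0.60), and Kcne3 was at 8.75 and 21.3 FPKM in tumour and listed at 0 in brain. Tip cell genes lay at 1.65 (adjusted p = 6.09e-06; adjusted p = 0.0189 with an estimated correlation). Of 23 matrix genes, 4 rose and 0 fell (8 and 1 adjusted over the list alone), among them Col3a1 with 4.66 (SE 0.64), Mmp2 with 4.06 (SE 0.70) and Col18a1 with 3.74 (SE 0.66). Matrix genes lay at 1.43 (adjusted p = 4.16e-05; adjusted p = 0.0108 with an estimated correlation). Of 18 hypoxia and glycolysis genes, 4 rose and 0 fell (5 and 1 adjusted over the list alone), Car9, a hypoxia-induced carbonic anhydrase (2.80 and 11.8 FPKM in tumour, 0 in brain), Pgk1 with 1.53 (SE 0.33), Ldha with 1.47 (SE 0.33) and Hk2 with 2.82 (SE 0.74). The hypoxia list lay at 0.81 (adjusted p = 0.0149; adjusted p = 0.207 with an estimated correlation) and did not pass without knockout tumour replicate 2 (0.0734). Of 18 TGF-beta genes, Vim and Tgfbi rose by 2.15 (SE 0.30) and 4.29 (SE 0.81) and 0 fell (2 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.378). Of 12 immediate early genes, Egr1 fell by 2.69 (SE 0.41) and 0 rose, also adjusted over the list alone. That list did not pass (adjusted p = 0.0614), except without knockout brain replicate 3 (0.0459), with no filter (0.0348), with the neuron list (0.0144) or Y-linked transcripts (0.0281) as a covariate and with fry (0.0107).

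Of other cell types in knockout mice, 4 of 14 microglia and macrophage markers rose and 0 fell (10 rose adjusted over the list alone), with C1qa at 3.78 (SE 0.62) and Lyz2 at 5.20 (SE 0.88). Microglia markers lay at 2.58 (adjusted p = 5.44e-07; adjusted p = 0.00750 with an estimated correlation). Of 8 progenitor and glioma markers, 3 rose and 0 fell (5 and 1 adjusted over the list alone), Olig2 with 3.81 (SE 0.59), Cd44 with 3.25 (SE 0.72) and Nes with 1.77 (SE 0.49). That list lay at 1.10 (adjusted p = 0.0310; adjusted p = 0.110 with an estimated correlation) and did not pass without wild type tumour replicate 2 (0.0557). Of 10 neuron markers, Syt1 fell by 2.93 (SE 0.76) and 0 rose (2 fell adjusted over the list alone), with the list at -2.20 (adjusted p = 0.00137; adjusted p = 0.304 with an estimated correlation). Of 9 oligodendrocyte markers, 3 fell and 0 rose (4 fell adjusted over the list alone), among them Mobp with -2.85 (SE 0.73) and Mbp with -1.62 (SE 0.43). Oligodendrocyte markers lay at -1.58 (adjusted p = 0.00267; adjusted p = 0.315 with an estimated correlation). Of 9 astrocyte markers 0 passed, also adjusted over the list alone (list adjusted p = 0.378). Of 12 mural markers, Cspg4 rose by 3.21 (SE 0.60) and 0 fell, also adjusted over the list alone (list adjusted p = 0.258). Of 6 fibroblast markers, Col3a1 rose and 0 fell (2 rose adjusted over the list alone), and the list did not pass (0.81, adjusted p = 0.232), with a median of -0.40. Of 3 lymphocyte markers, Lck rose (24.5 and 9.04 FPKM, 0 in brain), and of 4 choroid plexus markers Ttr fell, while 0 of 3 erythrocyte markers passed. Adjusted over the list alone, Cd4 of the lymphocyte list was also lower (-2.51, SE 0.86), as was 1 erythrocyte gene, Hba-a2 (listed at 0 in tumour). Of the lists that did not pass in knockout, VEGF (adjusted p = 0.000242), venous (0.0225) and fibroblast lists (0.0181) passed with fry, VEGF with the neuron covariate (0.0271) and chemokines in a fit of the knockout libraries alone (0.0464). Of those that passed, glioma markers were lost with a pseudocount of 0.1 (0.0874), rescaling (0.0601), knockout libraries alone (0.0698) and without wild type tumour replicates 2 and 3 (0.0637), hypoxia with a filter of 5 FPKM (0.0778), adhesion GPCR (-0.35, 0.432) and oligodendrocytes (-0.55, 0.128) with the neuron covariate, and neurons (0.0742) and oligodendrocytes (0.0550) with fry.

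**Figure D3:**
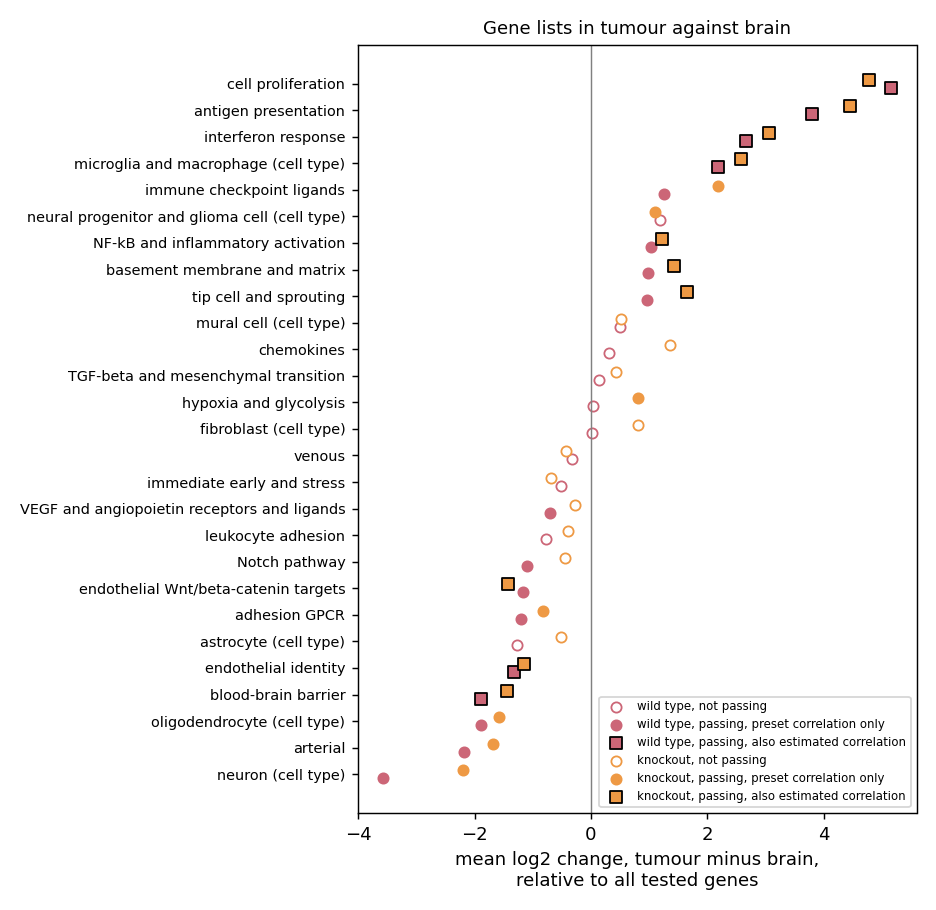
Mean log2 change of each gene list from brain to tumour, relative to all tested genes, in wild type and in knockout mice. Open circles did not pass, filled circles passed with the preset correlation only and squares also with an estimated correlation, and proliferation lies highest in both genotypes at 5.16 and 4.77.

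The 2 tumour against brain contrasts share no libraries. Of the genes called higher in tumour, 601 were shared between 1201 in wild type and 748 in knockout, where independent lists would share 57.6. Of the genes called lower, 281 were shared between 1823 and 357, where independent lists would share 41.7, and 0 genes were called in opposite directions. Top2a, Cd74, Gbp2 and Mcam were among the genes that rose in both, and Bsg, Slco1a4, Flt1 and Cldn5 among those that fell in both. Across 15604 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.756 and a Spearman rho of 0.716. The test of a difference between the genotypes is the interaction, given last.

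Knockout tumours were compared with wild type tumours, with the same limit. Knockout tumours had lower Adgrl4, and lists of endothelial identity, barrier, sprouting, matrix and antigen presentation genes, and of neuron and fibroblast markers, lay higher. Of the 27 lists, 11 passed with the preset and 0 with an estimated correlation (adjusted p of 0.144 to 0.393 for the 11), and single genes seldom passed. Limma called 3 genes, all higher in knockout (n = 2 and 3), and 485 genes had an unadjusted p under 0.05. Cox4i1, a subunit of mitochondrial cytochrome c oxidase on chromosome 8 from 120668225 to 120674209, was at 56.5 and 110 FPKM in knockout tumours and listed at 0 in the 3 wild type tumours (adjusted p = 0.00150). Ifi44l, an interferon-induced gene on chromosome 3 from 151758737 to 151762891, was at 33.6 and 19.9 FPKM and listed at 0 in wild type tumours (adjusted p = 0.0469).

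The remaining call, Rps15a-ps4, was named after its values were seen. It is a pseudogene of a ribosomal protein gene and was at 19.3 and 9.71 FPKM in knockout tumours and listed at 0 in every other library (adjusted p = 0.0309). Its near-identical copies make it uncertain. Ifi44l passed in 7 of 27 alternatives, and of the fits without 1 library only without wild type tumour replicate 2 or knockout brain replicate 1. Cox4i1 did not pass without knockout tumour replicate 2 (adjusted p = 0.0533) or in a fit of the tumour libraries alone (0.338). Fbxo31 (9.68 and 9.19 FPKM) and Rab4a (19.8 and 9.05 FPKM) were listed at 0 in wild type tumours and did not pass (adjusted p = 0.167 for both). Fbxo31 passed without wild type tumour replicate 2 (0.0357) and with no variance trend (0.0448), and both genes with a pseudocount of 0.1 (0.0384 for both) and with library weights (0.00295 and 0.00348). On the lower side, Samd12 was listed at 0 in knockout and at 4.26, 24.1 and 6.35 FPKM in wild type tumours (adjusted p = 0.659). Hoga1 was at 0 against 1.38, 53.2 and 5.88 FPKM. Egr1, an immediate early transcription factor, was at 5.75 ± 2.27 against 17.1 ± 1.60 FPKM (SD, n = 2 and 3; log2 difference -1.46, SE 0.41, adjusted p = 1), and none of these passed. With library weights, Adgrl4 (adjusted p = 0.0268) and Samd12 (0.0415) did. The count was 0 without knockout tumour replicate 2 (365 at an unadjusted p under 0.05), 29 without wild type tumour replicate 2, 12 without wild type tumour replicate 3, and 1 without wild type brain replicate 1, 2 or 3 or knockout brain replicate 2 or 3. It was 14 with no filter, 1 with a filter of 5 FPKM, after quantile normalization or with the neuron list or Y-linked transcripts as a covariate, 62 with library weights, 0 in a fit of the tumour libraries alone (411 at an unadjusted p under 0.05), and 19 without wild type tumour replicates 2 and 3.

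Cox4i1, Fbxo31 and Rab4a lie in the interval of chromosome 8 from Usp10 to Galnt2, 119910360 to 124345722 in GRCm38. In wild type tumour replicates 1 and 3, all 50 expressed genes of this interval of 4.44 Mb were listed at 0, against 10 in wild type tumour replicate 2, 2 in knockout tumour replicate 1 and 0 in knockout tumour replicate 2. The ribosomal protein gene Rpl13 was at 392 and 466 FPKM in knockout tumours and at 0, 448 and 0 in wild type tumours. Tubb3, a neuronal tubulin, was at 257 and 320 against 0, 293 and 0, and the amino acid transporter Slc7a5 at 89.7 and 77.3 against 0, 84.6 and 0. Within 5 Mb on either side, 37 of 37 expressed genes were above 0 in both libraries. Without the 67 tested genes of the interval, 0 genes passed between knockout and wild type tumours (445 at an unadjusted p under 0.05). Ifi44l and Rps15a-ps4 lie outside it, and Ifi44l kept its values there with an adjusted p = 0.0697.

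**Figure D4:**
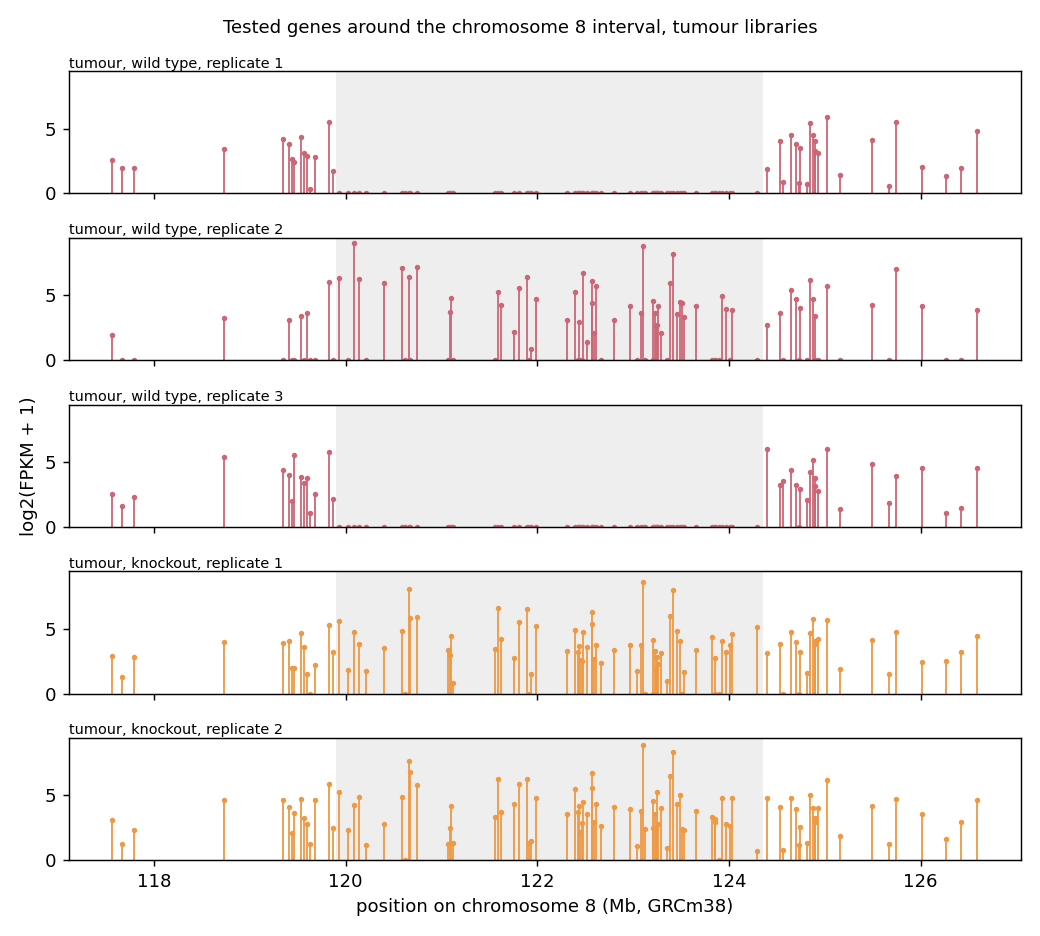
Log2(FPKM + 1) of tested genes along chromosome 8 (Mb, GRCm38) in the 5 tumour libraries, with the interval of 4.44 Mb shaded. In wild type tumour replicates 1 and 3 the genes of the interval are listed at 0.

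The 11 lists were relatively higher in knockout tumours, 0 passed with an estimated correlation and 6 with fry. The blood-brain barrier list lay at 0.48 (adjusted p = 0.000656; adjusted p = 0.144 with an estimated correlation), with a mean score per library of 4.80 and 5.10 in knockout and 4.15, 4.23 and 4.26 in wild type tumours. Of its 27 genes, 23 had log2 differences above 0 and 0 passed. Among them were the transferrin receptor Tfrc with 1.74 (SE 0.48), Abcg2 with 2.94 (SE 1.17) and Bsg with 0.80 (SE 0.32). Slc7a5 of the chromosome 8 interval is a member. Hypoxia and glycolysis lay at 0.73 (adjusted p = 0.000656; adjusted p = 0.144 with an estimated correlation), with 16 of 18 genes above 0. Adjusted over the list alone, 2 of them were higher, Car9 (2.80 and 11.8 FPKM, listed at 0 in wild type tumours) and P4ha2 with 2.92 (SE 0.68). Antigen presentation lay at 0.50 (adjusted p = 0.000674; adjusted p = 0.244 with an estimated correlation) with 16 of 16 above 0, such as Tap2 with 1.07 (SE 0.50) and B2m with 0.77 (SE 0.38). Tip cell genes lay at 0.58 (adjusted p = 0.00173; adjusted p = 0.144 with an estimated correlation) with 20 of 22 above 0, such as Plvap with 1.99 (SE 0.58), Kcne3 with 2.56 (SE 0.83) and Esm1 with 1.41 (SE 0.62). Endothelial identity lay at 0.33 (adjusted p = 0.00456; adjusted p = 0.144 with an estimated correlation) with 19 of 24 above 0, such as Ptprb with 1.95 (SE 0.74) and Eng with 1.69 (SE 0.70). Chemokines lay at 0.99 (adjusted p = 0.00489; adjusted p = 0.230 with an estimated correlation) with 8 of 9 above 0, such as Cxcl12 with 1.18 (SE 0.43). Matrix genes lay at 0.31 (adjusted p = 0.00577; adjusted p = 0.144 with an estimated correlation) with 20 of 23 above 0, such as Col1a1 with 1.62 (SE 0.51) and Sparc with 0.92 (SE 0.36). VEGF and angiopoietin genes lay at 0.41 (adjusted p = 0.0161; adjusted p = 0.144 with an estimated correlation) with 11 of 13 above 0, such as Ptprb and Tek, at 0.91 (SE 0.41). Arterial genes lay at 0.66 (adjusted p = 0.0203; adjusted p = 0.337 with an estimated correlation) with 11 of 13 above 0, such as Mgp with 2.81 (SE 0.87) and Efnb2 with 1.56 (SE 0.75). In the same libraries the neuron list lay at 1.20 (adjusted p = 0.0153; adjusted p = 0.393 with an estimated correlation) with 10 of 10 above 0, including Tubb3 of the interval, and without the interval lay at 0.77 and did not pass (0.0592). Its score was 4.82 and 6.04 in knockout and 2.51, 3.29 and 6.10 in wild type tumours. The fibroblast list lay at 0.94 (adjusted p = 0.00426; adjusted p = 0.144 with an estimated correlation) with 6 of 6 above 0, such as Col1a1.

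The calls rested on few libraries. Without wild type tumour replicate 3, 5 of the 11 lists passed. Endothelial identity (0.10, adjusted p = 0.348), tip cell (0.37, 0.231), VEGF (0.21, 0.273), matrix (0.09, 0.281), antigen presentation (0.07, 0.351) and arterial genes (0.0628) were lost, proliferation was lower (0.0152) and the neuron list lay at 2.15. Without knockout tumour replicate 2, 8 passed, with VEGF (0.0830), arterial (0.0637) and neuron lists (at 0.64, 0.477) lost and interferon response and checkpoint ligands higher (0.0384 for both). Without knockout tumour replicate 1, 9 passed, with endothelial identity and arterial lists lost (0.0654 for both). Without wild type tumour replicate 1, 9 passed, with VEGF (0.0806) and neuron lists (at 0.41, 0.807) lost and microglia higher (0.0435). Without wild type tumour replicate 2, 9 passed, with chemokines (from 0.99 to 0.37, adjusted p = 0.0997) and arterial genes (from 0.66 to 0.38, 0.115) lost, and VEGF, matrix and antigen presentation genes at 0.63, 0.56 and 0.76. Interferon response (0.0298), checkpoint ligands (0.00415), NF-kB (0.0369), TGF-beta (0.0440) and microglia (0.0298) were then higher and oligodendrocyte markers lower (0.00353), and without replicates 2 and 3 together 4 of the 11 passed, with the neuron list at 2.78 (2.80e-21). Chemokines (0.07, 0.896), antigen presentation (0.16, 0.575), tip cell (0.35, 0.357), hypoxia (0.32, 0.183), arterial (0.33, 0.166), endothelial identity (0.18, 0.0656) and fibroblast lists (0.0560) were lost there, chemokines (0.0789) and neurons (0.216) with the tumour libraries alone, VEGF with the Y-linked (0.0601) and arterial genes with the neuron covariate (0.0584). The microglia list, at 0.54 with all libraries, did not pass (adjusted p = 0.0545), but did without wild type brain replicate 1 (0.0402) or 3 (0.0342) or knockout brain replicate 2 (0.0415) or 3 (0.0450), the last of which also let checkpoint ligands pass (0.0410). Microglia markers also passed with no filter (0.0485), after quantile normalization (0.0129), in a fit of the tumour libraries alone (0.0157) and with the neuron covariate (0.00357). Interferon response (0.31, adjusted p = 0.0698), checkpoint ligands (0.71, 0.0731), NF-kB (0.16, 0.230), TGF-beta (0.06, 0.311), Notch (0.41, 0.196), leukocyte adhesion (0.21, 0.227), venous (0.11, 0.541), adhesion GPCR (0.25, 0.231), immediate early (-0.30, 0.147), mural (0.08, 0.589) and astrocyte lists (0.34, 0.227) did not pass. Nor did Wnt targets (0.617), proliferation (0.241), oligodendrocytes (0.501) and glioma markers (0.963), whose means of 0.07, 0.06, 0.21 and 0.13 lay above 0 and whose relative values of -0.19, -0.20, -0.05 and -0.13 lay below. Of these, interferon response (0.000397), checkpoint ligands (0.0281) and astrocytes (0.0491) passed after quantile normalization, interferon response in a fit of the tumour libraries alone (0.0138), checkpoint ligands with no filter (0.0159), and adhesion GPCR and astrocyte lists without wild type tumour replicates 2 and 3 (0.00243 for both). With the neuron covariate, interferon response (0.00439), checkpoint ligands (0.00133) and NF-kB (0.0263) were higher and oligodendrocyte markers lower (0.000886). Medians of proliferation, oligodendrocyte and glioma lists were -0.03, -0.02 and -0.06, and the glioma test pointed up. Over all genes 0 members of any list passed. Adjusted over the list alone, Il1b was higher, Adgrl4, Egr1 and the choroid plexus genes Ttr (listed at 0 in knockout) and Clic6 were lower, and in the other lists beside hypoxia 0 passed, lymphocyte and erythrocyte markers included.

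Knockout and wild type brains were compared next. Limma called 1 gene, which was not Adgrl4 (n = 3 and 3), and 679 genes had an unadjusted p under 0.05. The call, Gm15738, a predicted gene on chromosome 16 from 13392385 to 13422493, was named after its values were seen, and was at 14.7, 24.1 and 15.8 FPKM in knockout brains and listed at 0 in every other library (adjusted p = 0.0179). The helicase gene Recql stood at 26.8 ± 8.17 against 3.21 ± 2.35 FPKM (SD, n = 3 and 3; log2 difference 2.85, SE 0.52) and did not pass (adjusted p = 0.352).

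March3, a ubiquitin ligase gene (6.11, 5.02 and 6.68 FPKM), Tfr2, a transferrin receptor (3.34, 12.6 and 4.16 FPKM), and the immunoglobulin segment Igkv3-12 (21.7, 13.7 and 17.4 FPKM) were listed at 0 in wild type brain and did not pass (adjusted p = 0.352 for each), except Igkv3-12 without wild type tumour replicate 1 (0.0343). On the lower side, the actin-binding Cttn at 54.2 ± 11.4 against 161 ± 65.0 FPKM (SD, n = 3 and 3; log2 difference -1.49, SE 0.35), Zfp78 with -2.42 and Sumf2 with -3.95 (SE 0.95) did not pass. Of the 27 lists 0 passed, with the lowest adjusted p at 0.829 for endothelial identity (0.17), proliferation (0.19), venous (0.22), astrocyte (-0.43) and oligodendrocyte lists (-0.37), and the blood-brain barrier list at 0.03 (adjusted p = 0.915). Adjusted over the list alone, Cdk1 was higher (2.67, SE 0.51) and Adgrl4 lower, and 0 genes passed in the other lists. The count was 0 without knockout tumour replicate 1 or 2, wild type tumour replicate 3, wild type brain replicate 1 or knockout brain replicate 1 or 2, 2 without wild type tumour replicate 1 and 4 without knockout brain replicate 3. It was also 0 with a pseudocount of 0.1, a filter of 5 FPKM, a fit of the brain libraries alone (671 at an unadjusted p under 0.05), the neuron list or Y-linked transcripts as a covariate, or without wild type tumour replicates 2 and 3. Over all settings with 0 calls, 500 to 846 genes had an unadjusted p under 0.05.

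The difference of the genotype effect between tumour and brain was tested as an interaction. Cox4i1 was the only gene called (n = 2, 3, 3 and 3, adjusted p = 0.0234), and 496 genes had an unadjusted p under 0.05. Its FPKM in brain was 182, 338 and 118 in knockouts against 396, 173 and 163 in wild types. Of the lists, antigen presentation (0.64, adjusted p = 0.00918), hypoxia and glycolysis (0.77, 0.0115), tip cell (0.69, 0.0317), matrix (0.45, 0.0317), blood-brain barrier (0.45, 0.0464) and chemokines (1.06, 0.0494) had a higher genotype difference in tumour than in brain, each with an adjusted p = 0.389 with an estimated correlation. In the same libraries the neuron list lay at 1.37 and did not pass (0.0544). Without the chromosome 8 interval, the barrier (0.31, 0.0754) and chemokine lists (0.0534) were lost. Of the 6, matrix alone passed with fry. The interaction of Adgrl4 was -0.31 and did not pass.

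Cox4i1 passed in 11 of 25 alternatives, and of the fits without 1 library only without wild type tumour replicate 2 or knockout brain replicate 2. Where it was lost, limma called 1 other gene without knockout tumour replicate 1, 9 without wild type tumour replicates 2 and 3, and 0 elsewhere (373 to 1083 at an unadjusted p under 0.05 over all settings with 0), and it called 13 genes without wild type tumour replicate 2. Of the 28 alternatives, antigen presentation passed in 23, hypoxia and matrix in 21 each, tip cell in 20, barrier in 15 and chemokines in 12. Without wild type tumour replicate 3 (adjusted p of 0.0954 to 0.289) or wild type brain replicate 3 (0.0962 to 0.141), 0 of the 6 passed, and without knockout tumour replicate 2 antigen presentation alone. Without wild type tumour replicates 2 and 3, which left only replicate 1 in that group, chemokines, antigen presentation and hypoxia lay at 0.14, 0.30 and 0.36. The neuron list then lay at 2.95. The neuron list passed in 8 of 28 alternatives, in 1 of them with the direction turned, interferon response in 4, with 0.66 after quantile normalization (0.00278), proliferation and VEGF genes in 3 each, and fibroblast markers in 2 of 27. Adhesion GPCR (0.0109) and astrocyte lists (0.00220) passed without wild type tumour replicates 2 and 3, and endothelial identity (0.0155), checkpoint ligands (0.0146) and TGF-beta (0.0468) with the neuron covariate. Fbxo31, Ifi44l, Terc (3.52 and 10.1 FPKM in knockout tumours, 0 elsewhere), Recql with -3.66, Thap3 with -4.93, Igkv3-12 and March3 had the next smallest p and did not pass, except Igkv3-12 with library weights (0.0491) and without wild type tumour replicates 2 and 3 (0.0235). Across 15604 genes, not independent replicates, the genotype effects in tumour and brain had a Pearson r of 0.0066 and a Spearman rho of 0.011.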

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

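The tests of the chromosome 8 interval and of the mitochondrial mRNAs, and those of brain-cell RNA and of the loss of Eltd1 behind the knockout tumour lists, were chosen only after the results were seen. The following results stood out because the genotype effect differed between tumour and brain in the interaction test. Cox4i1 was listed at 0 in all wild type tumours, so its fitted log2 interaction of 6.52 depends on the pseudocount and is no exact change. Relative to all genes, the interaction was 0.45 for the blood-brain barrier list, 0.69 for tip cell and sprouting genes, 0.45 for basement membrane and matrix genes, 1.06 for chemokines, 0.64 for antigen presentation and 0.77 for hypoxia and glycolysis, and these 6 lists passed with the preset correlation and 0 of them with an estimated correlation. Without wild type tumour replicate 3 or wild type brain replicate 3, 0 of the 6 passed.

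The call of Cox4i1 belongs to the run of chromosome 8 genes listed at 0 in wild type tumour replicates 1 and 3. Low depth is argued against, since at most 1.72% of expressed genes outside the run were at 0 in either library. A deletion in the tumour cells is argued against by brain-rich genes, of which at least 94.8% were above 0 outside the interval in either library and 0 of 4 inside. All 50 expressed and 12 lower expressed genes inside were at 0 in both, including Rpl13 (228 to 466 FPKM elsewhere). Loss in some cells is argued against. Loss in processing cannot be told from loss in all brain and tumour cells, between the same borders in both libraries. Wild type tumour replicate 2 had 10 of the 50 at 0. No group cause was tested, so Cox4i1 cannot be called a genotype effect.

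Mitochondrial mRNAs summed to between 0 and 17.7 FPKM in tumour libraries and between 485 and 1199 in brain libraries. Less RNA of brain cells in tumour is argued against as the whole cause, because the share of the brain mean kept by neuron markers exceeded that kept by mitochondrial mRNAs by a median of 10.3 times over the 5 tumour libraries (from 1.41 in wild type tumour replicate 1, close to the 0.59 to 1.33 of brain libraries, over 3.97 and 10.3 in knockout to 90.7 in wild type tumour replicate 3, and without bound in replicate 2, with a sum of 0). A fall of the whole respiratory chain is argued against, since its 87 nuclear genes had a median log2 change of -0.64 in wild type and -0.57 in knockout mice. Separate handling cannot be told apart from tissue, since each tissue is its own set of libraries (lowest brain at 27.4 times the highest tumour library). Mitochondrial ribosomes lack L10a, so a fall in tumour endothelium itself cannot be tested here.

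Of the 27 lists, 11 were higher in knockout than in wild type tumours with the preset correlation, 0 of them with an estimated correlation, and 5 of them without wild type tumour replicate 3, the tumour library with the highest neuron score (6.10, against 6.04 in knockout tumour replicate 2). Few detected genes in wild type tumour replicate 2 are argued against as the whole cause, since without that library 9 of the 11 passed and the relative change without it over that with it had a median of 1.16 over the lists. More brain-cell RNA in the knockout tumour libraries stays open. With the neuron list as a covariate, 9 of the 10 other lists passed, a median of 2.76 standard errors above 0. Chemokines and arterial genes lay at 1.37 and 1.43. The covariate holds Tubb3, listed at 0 in wild type tumour replicates 1 and 3, so this test cannot decide. An earlier test, whether the neuron and oligodendrocyte lists move apart, was undecided at 1.25 standard errors. Loss of Eltd1 stays open too, since the exact permutation p of the barrier score was 0.1, the smallest that 2 against 3 libraries allow. That score includes Slc7a5 of the interval. A larger share of endothelial RNA in the knockout tumour libraries was not tested, and endothelial identity was among the 11 lists.

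For tumour against brain in wild type, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with 3024 calls against a highest other of 0. For knockout against wild type in brain it was also 1 of 10, with 1 call against a highest other of 0. Splits of 3 against 3 are too few for a share under 0.05.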

How the results depend on the processing

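The interval left out, both covariates and both tumour libraries (wild type replicates 2 and 3) left out were chosen after seeing the data. Of 139 alternative counts of genes, 73 lay within 1.5 times the reported count and 66 did not. Of 2004 values for named genes, 1856 kept their direction and side of the threshold, 133 no longer passed, 14 newly passed and 1 reversed. Of 3878 values for gene lists, 3635 kept both, 159 no longer passed, 79 newly passed and 5 reversed in the direction of the test. Tumour against brain in wild type gave 4937 genes with library weights, 614 with only the groups compared and 0 with the neuron covariate, and from 1796 to 3873 when 1 library was left out. In knockout it gave 710 with a pseudocount of 0.1, 1822 after quantile normalization, 4126 with library weights, 2803 with only the groups compared, 114 with the neuron covariate and 2750 without both tumour libraries, and from 163 to 2004 when 1 library was left out. Knockout against wild type in tumour gave 14 genes with no filter, 62 with library weights and 19 without both tumour libraries. It gave 1 with a filter of 5 FPKM, after quantile normalization, with the neuron covariate and with the Y-linked covariate, and 0 with only the groups compared and with the interval left out. It ran from 0 to 29 when 1 library was left out. In brain it gave 0 with a pseudocount of 0.1, a filter of 5 FPKM, only the groups compared, the neuron covariate, the Y-linked covariate and without both tumour libraries, and from 0 to 4 when 1 library was left out. The interaction gave 0 with no filter, quantile normalization, no variance trend, the interval left out and the neuron covariate, 4 with library weights and 9 without both tumour libraries, and from 0 to 13 when 1 library was left out. Where limma called 0 genes, those with an unadjusted p under 0.05 numbered 1119 for tumour against brain in wild type, 365 to 445 for knockout against wild type in tumour, 500 to 846 in brain and 373 to 1083 for the interaction. With the neuron covariate, Syp reversed to 0.62 in wild type tumour against brain, and the neuron list to -0.14 in knockout against wild type tumour and -0.052 in the interaction. For 2 lists in tumour against brain the calls were lost and the direction of camera's test turned, while the relative values shrank and stayed below 0, to -0.18 for oligodendrocytes in wild type (0.962) and to -0.041 and -0.093 for neurons in wild type (0.0851) and knockout (0.694). Checkpoint ligands in wild type turned from 1.26 to -0.26 (0.962). The neuron list shrinks by construction, since it is the covariate, and for the other changes the cause was not tested. That covariate differs between tumour and brain, so it also removes tissue differences. Of the named genes that passed, 0 of 24 in wild type and 10 of 24 in knockout still passed with it. In wild type Lamp5 and Atp1b1 shrank to -1.31 and -0.11, and the rest but Syp kept their sign at sizes of at least 4.49. Fits without 1 knockout tumour library assume that the remaining one varies like the other groups. No samples could be paired. Depth is unknown, so its effect on low values was not measured.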

Other observations

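The tests below were chosen only after the values were seen. Of 60 tested symbols of replication-dependent histone genes, whose mRNAs usually lack a poly(A) tail, 20 rose and 1 fell in wild type tumours with a median log2 change of 1.89, and 18 rose and 0 fell in knockout tumours with a median of 2.46, and the group was not tested as a set. Near-identical copies make single members uncertain. Sqstm1, which encodes the autophagy receptor p62, was the transcript with the highest FPKM in 4 of 5 tumour libraries. Its FPKM was 23800 and 5631 in knockout tumours and 21010, 21780 and 18360 in wild type tumours, against 742 to 1122 in brain, a log2 change of 4.35 (SE 0.42, n = 3 and 3) in wild type and 3.78 (SE 0.47, n = 2 and 3) in knockout mice. The maternally expressed RNAs Meg3 and Rian, of 1 imprinted cluster on chromosome 12, fell in tumour in wild type mice by 5.16 (SE 0.67) and 3.62 (SE 0.75) on the log2 scale, and in knockout mice by 4.34 (SE 0.75) and 4.69 (SE 0.84).

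Ifi44 and Ifi44l are neighbours of Adgrl4 on chromosome 3, 186 kb and 214 kb beyond its end. Ifi44l was higher in knockout tumours, and Ifi44 had a log2 difference of -1.99 between knockout and wild type brain that did not pass (adjusted p = 1). With the genotype effect averaged over both tissues, Adgrl4 had a log2 difference of -2.62 (SE 0.46) and ranked 6 of 15604 genes by p (adjusted p = 0.310). In that test limma called 1 gene, Cox4i1, and 529 had an unadjusted p under 0.05.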
